A study of Mus musculus with 4 samples.

How the data were processed

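RNA was measured in 4 libraries of mouse embryonic stem cells of the EB3 line: 1 parental, 1 with an empty vector and 2 that express NUP98-HOXA9. The libraries were made with a stranded poly(A) mRNA kit, per the labels' protocols. The authors deposited, for each library, a gene table with expected counts, TPM (abundance scaled by transcript length and depth) and FPKM (fragments scaled by length and depth), per the file headers. STAR 2.7.10a, RSEM 1.3.3, DESeq2 1.36.0 and genome build GRCm38/mm10 are named in the submitters' processing notes. The deposited expected counts are RSEM's estimates, in which reads that map to several genes are shared out, so 9.16% to 10.18% of values are not whole numbers. The annotation release, strand setting and filters are not given in the sources used here. The deposited FPKM values were not used in a test.

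The tables list 55401 gene identifiers, of which 55141 (99.5%) were matched to a GRCm38 annotation for symbols and coordinates. Libraries held 19021386 to 21151729 expected counts. The 10 most abundant genes took 5.3% to 6.58% of them, and mitochondrial genes 2.03% to 2.5%. Expected counts were rounded and tested with edgeR 4.0.16 in R 4.3.3, with TMM scaling, the filterByExpr filter at a minimum count of 10, and a robust quasi-likelihood fit. The 2 fusion libraries were set against the 2 wild-type libraries. P-values were adjusted by Benjamini-Hochberg over 16511 genes, with a threshold of 0.05. The common biological coefficient of variation was 25.6%, with 2 residual degrees of freedom and a median prior of 5.04. CPM values are TMM-scaled. The SE given with a log2 fold change is its absolute value divided by the square root of the quasi-likelihood F statistic. It was not estimated separately and may be too small for genes with few wild-type counts. For a gene with 0 counts in a group, the fold was taken against a floor of 3 counts over the group; with 1 to 3 counts the ratio is given with a 95% exact binomial interval. The design was tested on simulated data with known changes in 10 simulations.

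The comparisons, tests and 35 gene lists were fixed before the data were examined. They cover the 4 Hox clusters, their neighbours, Hox cofactors and ParaHox genes, leukaemia-associated partners and targets, and naive, core and formative or primed pluripotency. They also cover the 2-cell-like state, mesoderm, endoderm, trophectoderm, neural ectoderm, fibroblast markers, blood and endothelium, and germline genes. Response lists cover retinoic acid, Wnt, FGF-ERK, LIF-STAT3, TGF-beta and BMP, p53, interferon, unfolded protein, heat shock, and glycolysis and hypoxia. The others are cholesterol synthesis, cell cycle, nucleoporins, MLL and COMPASS, Polycomb, imprinted and Y-linked genes. The 33 lists with at least 5 tested members went through camera in limma 3.58.1 with a preset correlation of 0.01, two-sided, adjusted over the lists. The test was repeated with an estimated correlation and with fry, which asks whether a set's genes move on balance in 1 direction. Of the 13 lists past the preset test (10 higher and 3 lower), 0 passed with an estimated correlation and 1 passed fry.

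Genes were named by a rule. Nup98 and Hoxa9 were always named. Then came the 12 largest and 12 smallest log2 fold changes among genes with an official symbol, past the threshold, with a mean of at least 2 CPM and with both fusion libraries on the same side of both wild-type libraries. Chance puts 33.3% of genes in that last class. Up to 4 members past the threshold were named in a list past its test, 2 members in any other list, and up to 20 Hox genes past the threshold. Of the genes the rule names, 4 are not reported here, and neither the plot of Hox genes nor the counts of named genes across alternatives include them. The fusion was also set against each control alone in a fit with 3 groups. Pairs of libraries were compared by counting genes at least 2-fold apart among those at 1 CPM or more in the higher library, with a prior count of 2. Chromosome medians were taken of log2 ratios of each library to the mean of the other 3.

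Alternatives were DESeq2's size factors, library totals, no filter, a filter of 1 CPM in 2 libraries, a fit that is not robust, each control alone, each library left out in turn, a DESeq2 1.42.0 Wald test, and limma on log2 of the deposited TPM plus 1. A minimum fold of 2, a test against a fold of 1.5, a floor of 5 CPM for pairs and of 10 CPM for chromosomes were tried too. Tables were read with pandas 2.3.3 in python 3.11.15 and plots drawn with matplotlib 3.10.9.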

Results

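Messenger RNA was sequenced from EB3 cells, a mouse embryonic stem cell line grown on gelatin in medium with LIF, the cytokine that holds such cells in an undifferentiated state, and from EB3-derived cells that express NUP98-HOXA9. This fusion, known from acute myeloid leukaemia, joins the part of the nucleoporin NUP98 that is rich in phenylalanine-glycine repeats to the homeodomain of the transcription factor HOXA9. There were 4 libraries: 1 of the parental line, 1 of cells with an empty vector, and 2 of cells with the fusion (replicates 1 and 2). The libraries held 19957932 (parental), 19021386 (empty vector), 19820401 (fusion replicate 1) and 21151729 (fusion replicate 2) estimated counts. Genes with at least 1 count numbered 22939, 23263, 23775 and 24788 in the same order. The labels do not say whether the fusion libraries are separate clones or separate cultures, so the p-values measure only the spread between these samples. Among the wild-type libraries that spread lies between 2 kinds of control, parental and empty vector. Only 1 library, that with the empty vector, controls for the vector.

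The main comparison asked which genes differ between cells with the fusion (n = 2) and wild-type cells (parental and empty vector together, n = 2). In cells with the fusion, 20 genes of the HOXA, HOXB and HOXC clusters rose, and so did 15 of 21 tested endoderm genes, 8 of 19 genes of the retinoic acid response and 7 of 18 genes of the 2-cell-like state. Otx2, Pou3f1 and Dnmt3b, 3 of 15 tested genes of the formative and primed epiblast, fell, while Etv4 of the same list rose. Pou5f1, the central pluripotency factor, named after its values were seen, lay at 1020 and 1120 CPM (read counts scaled to library size by TMM) in the parental and empty-vector libraries and at 1080 and 940 CPM in fusion replicates 1 and 2. Of 16511 genes tested with edgeR's quasi-likelihood test, 564 passed a Benjamini-Hochberg adjusted p of 0.05. Of these, 468 were higher and 96 were lower in the fusion cells, so 83% of the calls were higher, and 464 and 88 of them differed at least 2-fold. The counts depend on the libraries and the tool: 163 genes passed without fusion replicate 1 (152 higher and 11 lower), 185 were lower without fusion replicate 2, and DESeq2 called 1355 genes (919 higher and 436 lower). In 10 simulated data sets of this design, on average over 16094 genes in the fit, 82.8% of 4-fold increases, 27.5% of 2-fold increases, 69.6% of 4-fold decreases and 20.1% of 2-fold decreases were recovered, and 11.5% of the calls were false. Each data set held 200 changed genes with a mean of at least 1 CPM, and both wild-type libraries were drawn from the same mean. These shares need not hold for the real calls, where the controls differ and some genes are near 0 in wild-type cells.

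Hoxa9 itself (chromosome 6, 52223100 to 52231089, minus strand) had 0 counts in both wild-type libraries and stood at 190 CPM in fusion replicate 1 and 127 CPM in replicate 2. That is at least 1990-fold higher when the wild-type group is set to a floor of 3 counts over the group (adjusted p = 0.00162, edgeR). Nup98 stood at 216 and 218 CPM in the wild-type libraries and at 310 and 296 CPM in the fusion libraries. Its log2 fold change of 0.48 (SE 0.16) did not pass (adjusted p = 0.161). Reads from the construct and from the cells' own genes are not separated in these gene-level counts, and the labels do not give the species of the fused sequences. Intervals and floors in this text cover counting error only.

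Of the 39 Hox genes, the homeobox genes that pattern the body axis, 28 were tested; 20 rose and none fell (25 and 0 adjusted over the list alone). Among all other genes tested, 448 of 16483 rose, giving an odds ratio of 89.3 for Hox genes (one-sided Fisher exact p = 1.89e-25, across genes, which are not independent). Few tested Hox genes reached a mean of 1 CPM in the wild-type libraries: 1 each of HOXA, HOXB and HOXC, and 0 of HOXD. Most therefore passed the count filter through the fusion libraries and had little room to fall. The counts of rises and falls and the odds ratio are partly fixed by that filter. So are the medians and set tests of the clusters given below. All 10 tested genes of the HOXA cluster rose (10 adjusted over the list alone). Hoxa10 went from 0 and 0.159 CPM in the wild-type libraries to 46.5 and 47.8 CPM in the fusion libraries, and Hoxa7 from 0.469 and 0.796 to 66.2 and 30.3 CPM. Hoxa3, Hoxa5, Hoxa2, Hoxa4, Hoxa6 and Hoxa11 rose too, with adjusted p between 0.00242 and 0.0215. Hoxa3 had 1 count over the wild-type group and 2252 over the fusion group, a ratio of 2050 (95% exact binomial interval 367 to 80900). In the HOXB cluster 7 of 10 tested genes rose (10 adjusted over the list alone): Hoxb1, Hoxb2, Hoxb3, Hoxb4, Hoxb5, Hoxb8 and Hoxb9. Hoxb8 reached 19 CPM in fusion replicate 1 and 2.05 CPM in replicate 2, against 0.0521 and 0.053 CPM in the wild-type libraries. In the HOXC cluster Hoxc4, Hoxc6 and Hoxc10 rose, 3 of 6 tested genes (5 adjusted over the list alone). Hoxc4 went from 0.104 and 0.106 to 7.12 and 2.28 CPM. Of the HOXD cluster only Hoxd1 and Hoxd13 could be tested, and neither passed (adjusted p = 0.263 and 0.367; 0 adjusted over the list alone).

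The clusters differed between the fusion libraries. The HOXA genes summed to 510 CPM in replicate 1 and 324 CPM in replicate 2, against 2.08 and 2.65 CPM in the parental and empty-vector libraries. Hoxa9, whose reads may come from the construct, supplied 190 and 127 CPM of the fusion sums. The HOXB genes summed to 78.3 and 23.7 CPM, a 3.31-fold difference between the fusion libraries, and the HOXC genes to 39 and 9.76 CPM. HOXC lies on the part of chromosome 15 whose genes stood higher in fusion replicate 1. The median log2 fold change was 9.05 for HOXA (6.85 with genes of 0 wild-type counts at their bound), 6.65 for HOXB (5.36 at the bound) and 5.35 for HOXC. Genes with 1 to 3 wild-type counts kept their fitted values in these medians. As sets, all 3 clusters passed the camera test with a preset correlation (adjusted p = 1.79e-65 for HOXA, 2.75e-14 for HOXB and 1.02e-05 for HOXC). With an estimated correlation the adjusted p was 0.234 for HOXA, 0.431 for HOXB and 0.582 for HOXC. The HOXA median and set tests include Hoxa9 and were not repeated without it. The count of Hox genes that rose was 10 without fusion replicate 1. The annotated spans of Hoxa3 overlap Hoxa4, Hoxa5 and Hoxa6, and those of Hoxc5 overlap Hoxc6, Hoxc8 and Hoxc10, on the same strand, so counts within these groups are uncertain. Of 16 tested genes next to the clusters, Calcoco2 rose (log2 2.35, SE 0.4, adjusted p = 0.0319) and Skap2 had a log2 fold change of 1.34 (adjusted p = 0.0507), and the set did not pass (adjusted p = 0.783; 2 higher and 2 lower adjusted over the list alone). With DESeq2's size factors or library totals, 2 of these neighbours rose.

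**Figure D1:**
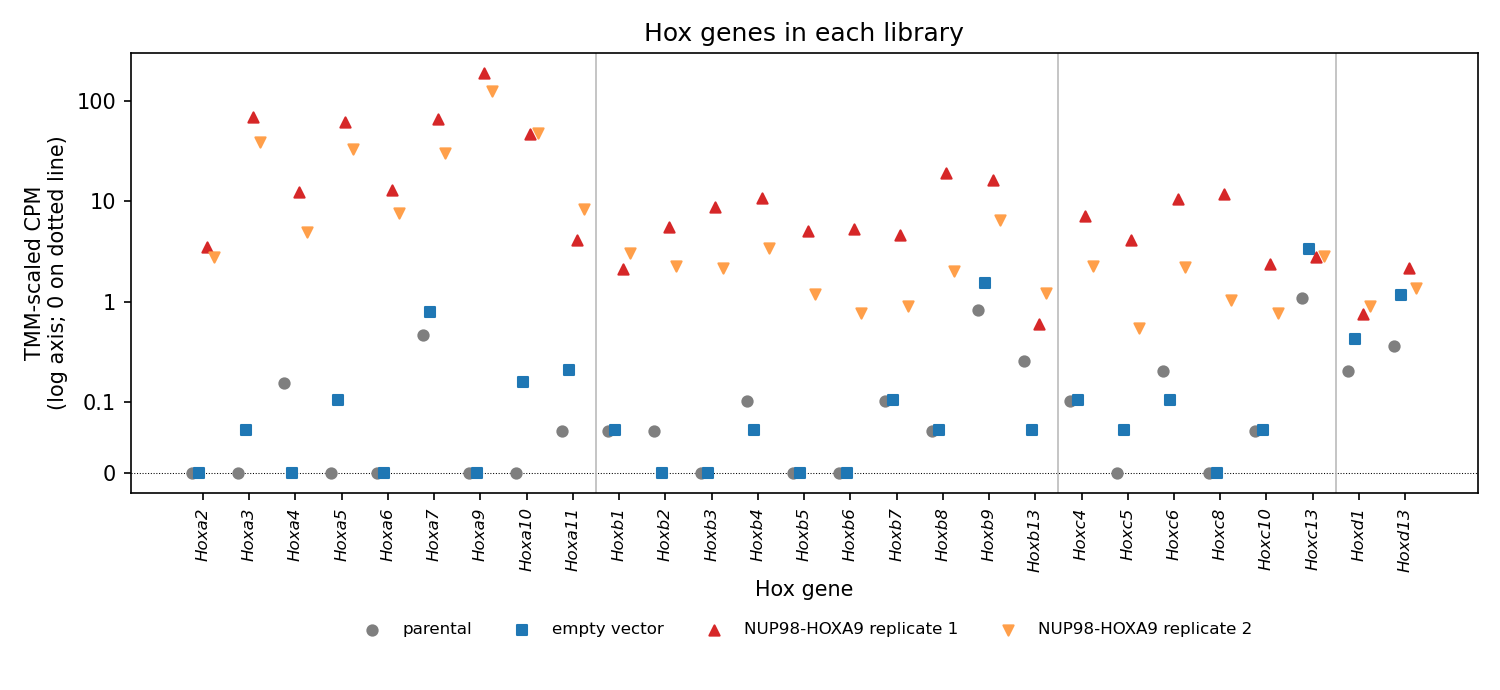
TMM-scaled CPM of tested Hox genes in the 4 libraries (log axis; libraries with 0 counts are drawn on the dotted line), with vertical lines between the clusters. The fusion libraries lie above both wild-type libraries for the plotted genes that rose, and Hoxa9 is at 190 and 127 CPM in them.

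Outside the Hox clusters, the 12 largest increases by the naming rule included Stra8, Srgn, Glipr1 and Bhmt, beside 7 Hox genes and the antisense transcript Hoxa11os. Stra8, a retinoic acid-induced gatekeeper of meiosis, went from 0.469 and 0.318 CPM to 142 and 162 CPM (log2 8.57, SE 0.29, adjusted p = 0.000222). Srgn, which encodes the proteoglycan serglycin, had 2 counts over the wild-type group and 723 over the fusion group, a ratio of 328 (95% exact binomial interval 90.6 to 2720). Glipr1 had 2 and 373 counts, a ratio of 169 (interval 46.6 to 1400), and Bhmt, a betaine-homocysteine methyltransferase, had 1 and 187, a ratio of 170 (interval 30.1 to 6750). Hoxa11os had 0 and 235 counts, at least 71.2-fold higher; whether strand was used in counting is not given in the sources used here, so its reads may include those of its sense partner Hoxa11.

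The largest decreases by the naming rule included Prlr, Trh, Enpp2, Kctd12b, Pmel, Otx2, Myb, Neb, Pla2g4a, Aim2 and Prdm1. Trh, which encodes thyrotropin-releasing hormone, fell from 953 and 476 CPM to 20.9 and 56 CPM (log2 -4.21, SE 0.55, adjusted p = 0.0158). Otx2, a homeodomain factor of the primed epiblast and anterior neural tissue, fell from 61.3 and 78 CPM to 3.66 and 11.4 CPM (log2 -3.2, SE 0.5, adjusted p = 0.0259). Myb, a regulator of blood progenitors, fell from 20.7 and 16.4 to 1.45 and 2.78 CPM, and Prdm1, which encodes BLIMP1, from 39.2 and 30.3 to 1.8 and 7.16 CPM. Pmel, a melanosome protein, fell from 68.7 and 32.1 to 2.91 and 5.75 CPM. The other 6 of these had log2 fold changes from -4.78 (Prlr) to -3.04 (Aim2), with adjusted p between 0.0264 (Aim2) and 0.0483 (Prlr).

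Endoderm genes rose in both fusion libraries. Of 21 tested markers of definitive and primitive endoderm, 15 rose and none fell (18 and 1 adjusted over the list alone), with a median log2 fold change of 3.77. The 1 lower over the list alone was Apoe, named after its values were seen. Its mean was 785 CPM in the wild-type and 369 CPM in the fusion libraries (log2 -1.09, adjusted p = 0.075, edgeR). Of the 21, 11 reached a mean of 1 CPM in the wild-type libraries, and the others had little room to fall. The median and the set test share this limit. Col4a1 and Col4a2, the collagen IV chains of basement membrane, rose from 25 and 18.2 to 384 and 307 CPM and from 12.2 and 7.16 to 211 and 169 CPM. Gata6, a transcription factor that directs primitive endoderm, rose from 0.469 and 0.212 to 20.7 and 26 CPM (log2 6.07, SE 0.45, adjusted p = 0.00476). Lama1, a laminin chain, rose from 48.9 and 47.2 to 227 and 206 CPM. The set passed the camera test (adjusted p = 6.49e-36; adjusted p = 0.168 with an estimated correlation), and it was the only list past fry's directional test (adjusted p = 0.034). Col4a1 and Col4a2 lie on chromosome 8, whose genes had a higher median in the parental library. A higher level in a control would lessen a rise in the fusion libraries, not give one. Against the empty vector alone, Col4a1 and Col4a2 had log2 fold changes of 4.24 and 4.73.

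In the list of retinoic acid response genes, 8 of 19 tested rose and none fell (15 and 0 adjusted over the list alone), with a median log2 fold change of 3.14. Of the 19, 12 reached a mean of 1 CPM in the wild-type libraries, and the others had little room to fall, which also limits the median and the set test. Aldh1a2, the enzyme that makes retinoic acid in the embryo, rose from 3.59 and 4.14 to 378 and 109 CPM (log2 5.97, SE 0.63, adjusted p = 0.00883). Cdx1, a caudal-type homeobox gene, rose from 1.09 and 0.53 to 116 and 42.7 CPM, and Stra8 is a member too. The camera adjusted p was 8.81e-27 (adjusted p = 0.267 with an estimated correlation). With the Hox and Cdx members left out, a choice made after seeing the data, it was 9.9e-19. Of 12 tested Hox cofactors and ParaHox genes, Cdx1 and Pbx3 rose (7 adjusted over the list alone); Pbx3, a DNA-binding partner of Hox proteins, went from 14.4 and 10.9 to 60.2 and 42.8 CPM. That set had a median log2 fold change of 0.86 and passed (adjusted p = 3.77e-06; adjusted p = 0.582 with an estimated correlation). Of 23 tested germline genes, Stra8, Dazl and Brdt rose and Prdm1 fell, though none fell with library totals (8 higher and 2 lower adjusted over the list alone). Dazl, an RNA-binding protein of germ cells, went from 4.74 and 5.14 to 21.9 and 22.6 CPM, and the set had a median of 0.68 and passed (adjusted p = 2.29e-05; adjusted p = 0.582 with an estimated correlation). With Stra8 left out, also chosen after seeing the data, the germline set had an adjusted p of 0.0261.

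The 2-cell-like state is a rare state of embryonic stem cells that resembles the 2-cell embryo. The 7 genes of its list that passed were higher in both fusion libraries and highest in replicate 2. Of 18 tested, 7 rose and none fell (17 and 0 adjusted over the list alone), with a median log2 fold change of 4.39. Zfp750, named after its values were seen, had a log2 fold change of -1.75 (adjusted p = 0.299). Of the 18, 8 reached a mean of 1 CPM in the wild-type libraries, and the others had little room to fall, which also limits the median and the set test. With DESeq2's size factors 11 rose, and with library totals 5. Zscan4c went from 1.67 and 3.29 CPM to 22 CPM in fusion replicate 1 and 117 CPM in replicate 2 (log2 4.81, SE 0.82, adjusted p = 0.0327). Zscan4e went from 0.938 and 2.6 to 16.1 and 93.8 CPM, Tmem92 from 0.26 and 0.53 to 4.66 and 17.5 CPM, and Zfp352 from 0.0521 and 0.159 to 1.3 and 1.78 CPM. The Zscan4 genes are near-identical copies, so the split of reads between them is uncertain. Members of the Zscan4 and Usp17l families make up much of the list and of the genes that rose. The counts of genes and the set test therefore do not rest on independent genes. The set passed (adjusted p = 2.59e-14; adjusted p = 0.582 with an estimated correlation).

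Weaker sets were those of glycolysis and hypoxia and of trophectoderm. Slc2a3, a glucose transporter, rose from 1180 and 1500 to 3190 and 3610 CPM. Vegfa, P4ha1 and P4ha2 also rose, giving 4 of 27 tested genes of glycolysis and hypoxia (9 adjusted over the list alone). Vegfa, the endothelial growth factor, went from 34.6 and 21.4 to 89.1 and 110 CPM. The set's median log2 fold change was 0.32 (adjusted p = 0.000248; adjusted p = 0.633 with an estimated correlation), and without fusion replicate 2 its adjusted p was 0.11. None of 17 tested trophectoderm genes passed (2 with DESeq2's size factors; 4 higher adjusted over the list alone), though the set did (median 0.72, adjusted p = 0.0186; adjusted p = 0.601 with an estimated correlation). Its adjusted p was 0.0711 with a filter of 1 CPM in 2 libraries and 0.406 against the parental line alone. It was 0.402 without the empty-vector library, 0.0888 without fusion replicate 1, and 0.12 without members that other lists share, the last a choice made after seeing the data.

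The 3 remaining sets that passed were lower in the fusion cells. Of 15 tested genes of the formative and primed epiblast, Otx2, Pou3f1 and Dnmt3b fell and Etv4 rose (7 lower and 1 higher adjusted over the list alone). Dnmt3b, a de novo DNA methyltransferase, fell from 405 and 517 to 172 and 231 CPM, and Pou3f1, a POU-domain factor, from 28.1 and 32.2 to 10.5 and 12.2 CPM. Etv4, an ETS factor, rose from 51.3 and 32.5 to 200 and 129 CPM. The median was -0.83 (adjusted p = 0.000132; adjusted p = 0.582 with an estimated correlation). The nucleoporin and exportin genes had no member past the test among 32 (0 adjusted over the list alone), with a median of -0.2 (adjusted p = 0.00981; adjusted p = 0.582 with an estimated correlation; 0.141 without fusion replicate 2). Of 15 tested interferon-response genes, Ddx58, which encodes the RNA sensor RIG-I, fell from 57 and 56.5 to 10.9 and 7.48 CPM, and Irf1 from 50.6 and 38.9 to 18.7 and 19.5 CPM (2 lower adjusted over the list alone). That set had a median of -0.29 (adjusted p = 0.0364; adjusted p = 0.582 with an estimated correlation), with an adjusted p of 0.188 without the parental library and 0.0763 without fusion replicate 2. Its adjusted p was 0.191 against the empty vector alone and 0.0641 by limma on TPM.

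**Figure D2:**
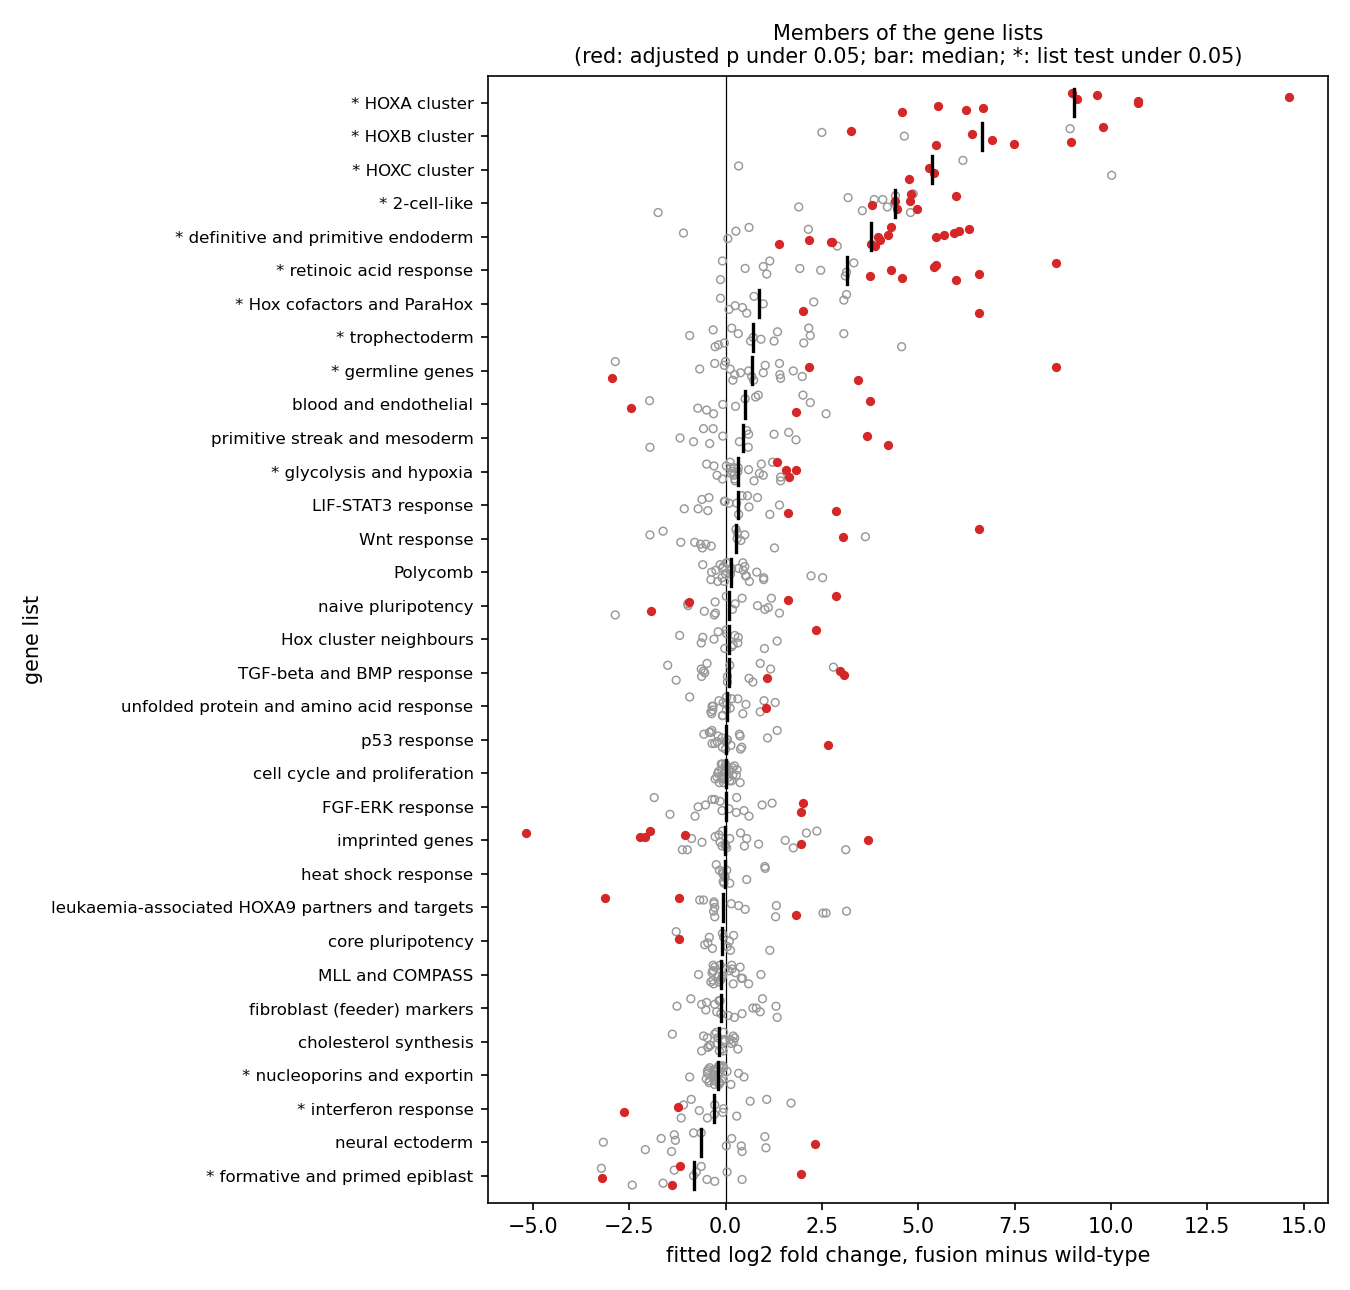
Fitted log2 fold change, fusion minus wild-type, of each tested member of the 33 gene lists, with members past an adjusted p of 0.05 filled in red, medians as black bars and an asterisk on the 13 lists past the camera test with a preset correlation. Fitted values of genes with 0 wild-type counts depend on the prior count, and the medians run from -0.83 for the formative and primed epiblast to 9.05 for the HOXA cluster.

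The remaining lists did not pass, and several held members that moved in both directions. Genes named here beyond the 2 with the smallest p in each list were chosen after their values were seen. Of 20 tested naive pluripotency genes, Tbx3 and Klf5 rose, and Tdh and Nr5a2 fell, 1 of them with library totals (7 higher and 4 lower adjusted over the list alone; set adjusted p = 0.785). Tbx3, a T-box factor, went from 47.6 and 82.5 to 524 and 418 CPM, and Tdh, the threonine dehydrogenase of embryonic stem cells, from 677 and 738 to 163 and 209 CPM. Among 13 core pluripotency genes Lin28a fell, from 372 and 281 to 130 and 154 CPM, and Dppa2 had a log2 fold change of 1.15 (adjusted p = 0.0543; set adjusted p = 0.229; 1 higher and 1 lower adjusted over the list alone). Of 29 tested imprinted genes, Rian and Meg3, long noncoding RNAs of the Dlk1-Dio3 locus, fell, as did Mirg, Impact and Nnat, while Cdkn1c and Igf2 rose (6 higher and 6 lower adjusted over the list alone; set adjusted p = 0.421). Meg3 went from 297 and 346 to 80.4 and 69.4 CPM, and Rian from 359 and 412 to 87.4 and 79.4 CPM.

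Of 18 tested leukaemia-associated partners and targets of HOXA9, Kit rose from 45.9 and 53.6 to 198 and 158 CPM, and Myb and Cdk6 fell (4 higher and 3 lower adjusted over the list alone; set adjusted p = 0.783). In the blood and endothelial list Kit and Cdh5 rose and Tek fell among 15, though none fell with library totals (5 higher and 2 lower adjusted over the list alone; set adjusted p = 0.125, and 0.0292 without fusion replicate 1). Cdk6 and Tek were named after their values were seen. Pdgfra and Wnt3a rose among 16 genes of primitive streak and mesoderm (3 higher and 1 lower adjusted over the list alone; set adjusted p = 0.125). Without the parental library that set had an adjusted p of 0.00886, and without fusion replicate 2 of 0.0489. Pdgfra is also on the endoderm list. Sox1 rose among 15 neural ectoderm genes (1 higher and 4 lower adjusted over the list alone; set adjusted p = 0.229, and 0.0143 without the parental library), while Dll3 had a log2 fold change of -1.67 (adjusted p = 0.125). None of 19 fibroblast markers, which would report feeder cells, passed (0 adjusted over the list alone; set adjusted p = 0.915); the smallest p belonged to Ccn2 and Loxl1 (both adjusted p = 0.146). Among response genes, Cdx1 and Zfp703 rose in the Wnt list of 17 (4 higher and 3 lower adjusted over the list alone; set adjusted p = 0.549). Etv4 and Phlda1 rose in the FGF-ERK list of 18 (3 higher and 1 lower adjusted over the list alone; set adjusted p = 0.699). Tbx3 and Klf5 rose in the LIF-STAT3 list of 18 (4 higher and 2 lower adjusted over the list alone), whose adjusted p was 0.158, 0.0218 without the empty-vector library and 0.00432 without fusion replicate 2. Smad6, Smad7 and (named after its values were seen) Msx2 rose in the TGF-beta and BMP list of 18 (3 adjusted over the list alone), whose adjusted p was 0.309, and 0.0401 without fusion replicate 2. Smad6, an inhibitor of BMP signalling, went from 4.48 and 3.98 to 37.2 and 29 CPM.

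Sesn1 rose among 22 p53 targets (3 adjusted over the list alone; set adjusted p = 0.456), with Plk3 at a log2 fold change of 1.34 (adjusted p = 0.0668). Xbp1 rose among 22 genes of the unfolded protein and amino acid response (1 adjusted over the list alone; set adjusted p = 0.663, and 0.0227 without the parental library). Atf3 had an adjusted p of 0.21. The p53 set was higher at an adjusted p of 0.000327 without the empty-vector library and lower at 0.0495 without the parental library. No gene of the next 5 lists passed, except 1 of the MLL and COMPASS list with library totals. Of 13 heat shock genes, Hspb1 and Hspa1b had adjusted p of 0.0701 and 0.0903 (2 higher adjusted over the list alone; set adjusted p = 0.783). Of 24 cholesterol synthesis genes, Idi1 had an adjusted p of 0.246 (0 adjusted over the list alone; set adjusted p = 0.358). That set was lower at an adjusted p of 9.19e-07 without the empty-vector library and higher at 0.0349 without the parental library. Of 28 cell cycle genes, Cdk1 and Ccnb1 had adjusted p of 0.271 and 0.44 (0 adjusted over the list alone; set adjusted p = 0.783). Of 26 MLL and COMPASS genes, which encode histone methyltransferases and their partners, Ncoa6 and Dpy30 had adjusted p of 0.0504 and 0.101 (1 higher adjusted over the list alone; set adjusted p = 0.565). Of 28 Polycomb genes, Phc2 had an adjusted p of 0.0833 (4 higher adjusted over the list alone; set adjusted p = 0.262). The 4 tested Y-linked genes were too few for a set test, and none passed, with Uba1y and Eif2s3y at adjusted p of 0.224 and 0.442 (0 adjusted over the list alone).

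Set against each control alone, the fusion libraries showed the same direction for every gene called in the main comparison: all 564 kept their sign against the empty vector and against the parental line. This was largely fixed in advance, since all 564 had both fusion libraries on the same side of both wild-type libraries. Against the empty vector 82 genes passed, 64 higher and 18 lower, and 75 of them were main calls in the same direction. Against the parental line 104 passed, 84 higher and 20 lower, and 83 of them were main calls in the same direction. Stra8 had a log2 fold change of 8.87 against the empty vector and 8.32 against the parental line, and Col4a1 of 4.24 and 3.79. These counts depend on the processing. Against the empty vector they ran from 13 with library totals to 1553 with no low-count filter, with 162 in a fit that is not robust and 221 with DESeq2's size factors. Against the parental line the same settings gave 29, 1671, 160 and 281. With the other control left out of the data altogether, 447 genes passed against the empty vector and 475 against the parental line. In these fits the spread comes only from the 2 fusion libraries, with 1 residual degree of freedom, and the lone control is assumed to vary like them. The main calls rest on these same libraries, so they are not independent evidence.

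Single pairs of libraries, which have no replicate check, put these differences on a scale. Between the parental and empty-vector libraries 1245 genes (8.5% of those at 1 CPM or more in the higher library) were at least 2-fold apart, and between the fusion libraries 1462 (9.6%). Between a fusion and a control library the number ran from 2425 to 3302 (15.9% to 21.8%). Across genes, the correlation of log CPM was 0.974 between the controls, 0.971 between the fusion libraries and 0.921 to 0.943 between a fusion and a control library; genes are not independent replicates.

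Chromosome medians also differed between libraries. Genes of chromosome 8 had a median log2 ratio of 0.35 in the parental library against the mean of the other 3, and genes of chromosome 15 a median of 0.34 in fusion replicate 1. On every other autosome the medians of all libraries lay between -0.08 and 0.12. Chromosome 8 held 16 of the genes called higher and 2 called lower in the fusion cells, and chromosome 15 held 26 and 4. HOXC lies on chromosome 15. Col4a1 and Col4a2 lie on chromosome 8, where the higher parental median would lessen their rise, not give it. With both chromosomes left out of the count, a choice made after seeing the data, 516 genes passed, 426 higher and 90 lower.

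**Figure D3:**
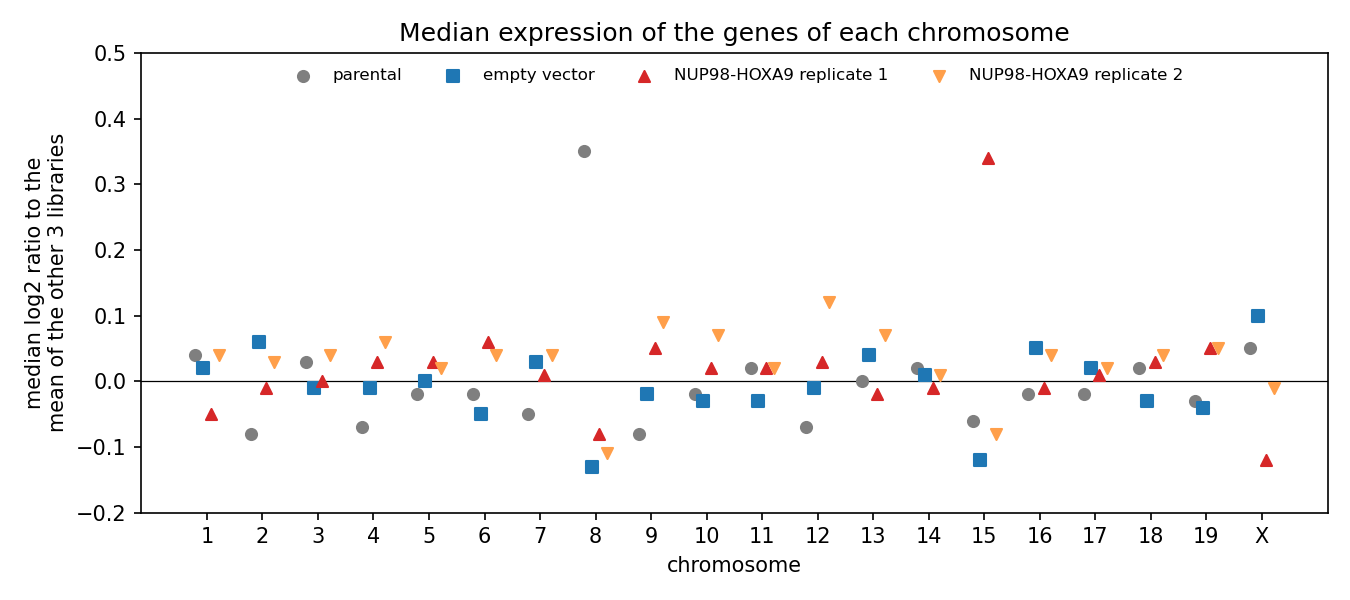
Median log2 ratio of the genes of each chromosome in each library to the mean of the other 3 libraries. The parental library stands at 0.35 on chromosome 8 and fusion replicate 1 at 0.34 on chromosome 15.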

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

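The counts without chromosomes 8 and 15, and the retinoic acid, trophectoderm and germline lists without some members, were chosen after seeing the data. No paired analysis was possible because the labels pair no libraries. The count of 564 genes changed ran from 535 to 646 under DESeq2's size factors, library totals, the 1 CPM filter, the fit that is not robust, limma on TPM and a minimum fold of 2, and was 516 without chromosomes 8 and 15. The genes themselves were less stable than their number. Of the 564, limma on TPM also called 427, with 16 Hox genes higher, library totals 512 and the 1 CPM filter 538. The count of genes changed was 1946 (1315 higher, 631 lower) with no filter, 1355 (919 and 436) by DESeq2, 82 (64 and 18) against the empty vector alone, 104 (84 and 20) against the parental line alone, and 254 against a fold of 1.5; the cause was not tested. Leaving out each library in turn gave 163 to 552 genes changed, 152 to 367 higher and 11 to 185 lower, the lowest each time without fusion replicate 1; the lone library left is assumed to vary like the other group. Hox genes that rose numbered 6 against the empty vector and 7 against the parental line, and 10 to 25 with a library left out.

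The number of lists past the threshold was 0 with an estimated correlation and 1 with fry, and 12 to 17 under the other alternatives; DESeq2 was not run on lists. The cholesterol list turned higher against the empty vector (adjusted p 0.0248), and its adjusted p ran from 9.19e-07 to 0.499 with a library left out. That of the p53 list ran from 0.000327 to 0.797, and it turned lower without the parental library. The 95 genes named by the rule and reported here kept their sign in every setting that tested them. All 564 main calls had both fusion libraries on the same side of both wild-type libraries. For the named genes past the threshold a kept sign was therefore largely fixed in advance. Of the 75 past the threshold, 55 missed the threshold against the empty vector and 48 against the parental line. Against the empty vector, 221 genes passed with DESeq2's size factors, 13 with library totals, 1553 with no filter and 162 with the fit that is not robust; against the parental line the counts were 281, 29, 1671 and 160, and the cause was not tested.

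At a floor of 5 CPM the genes 2-fold apart numbered 615 between the controls and 751 between the fusion libraries. Replicates 1 and 2 differed from the parental library in 1971 and 1296 genes and from the empty-vector library in 1826 and 1343, fewer genes being counted. The chromosome 8 median of the parental library was 0.41 at 10 CPM or more. In simulated data of this design 27.5% of 2-fold increases were recovered; what depth limits was not tested, since depth was not varied.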

Other observations

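The tests on endoderm genes, on 2-cell-like genes, on HOXC and on other splits of the libraries were chosen after the result was seen. Those on parts of chromosomes 8 and 15 were set before the parts were examined. These chromosomes were picked because their medians stood out in the same data.

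Gm49089, a transcript of unknown coding status on chromosome 15 (33831448 to 33834353, plus strand), singled out after its values were seen, rose from 0.104 and 0.265 CPM in the wild-type libraries to 504 and 306 CPM in the fusion libraries (log2 11.06, SE 0.48, adjusted p = 0.000545). Its transcript of 2906 nt shares at least 200 nt at 90% identity or more with 7 other genes. The 3 of these that were tested all rose: Olfr1459 (2933 nt aligned at 95.2%; log2 6.95), G430049J08Rik (2690 nt at 96.6%; log2 7.58) and Gm14300 (946 nt at 96.2%; log2 5.36). Reads shared between such copies were not separated.

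Endoderm genes rose in both fusion libraries. More cells of every differentiated type alike would raise the mesoderm, neural ectoderm and trophectoderm lists as well. Their 45 members had a median log2 fold change of 0.33, against 3.77 for the 21 endoderm members. Pdgfra, which rose, was counted with endoderm. The difference was -3.44 (two-sided permutation p = 1e-05, the smallest that 100000 permutations can give). The permutation treats members as independent, which genes are not, and endoderm was singled out after it rose. That p-value therefore overstates the evidence, and the medians show only that the lists did not rise alike. Whether a single kind of cell of fixed make-up is present at another share in each library cannot be told apart from genes that vary singly. The excess over wild-type in replicate 2 over replicate 1 had a median of 0.883 and ran from 0.145 for Hnf4a to 12.7 for Cubn. The SD of its log2 was 1.44, above 98.7% of 10000 sets of other genes that rose, matched on CPM in the fusion libraries. The median absolute deviation of 0.84 was above 74.1% of them, so a few genes carry the SD. Partial activation in most cells may also remain, which was not tested.

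All 2-cell-like genes that rose were highest in fusion replicate 2. Reads moved between copies of Zscan4 would leave their sum alike, but the 9 copies summed to 10.8 and 28.3 CPM in the wild-type libraries and to 150 and 772 CPM in the fusion libraries, 5.32-fold from the higher control to the lower fusion library. For the 7 genes that rose, the excess in replicate 2 over replicate 1 ran from 1.4 to 6.41 (median 4.88). Most of the 7 belong to the Zscan4 or Usp17l family, so their ratios are not independent. The SD of its log2 was 0.75, above 29.4% of matched sets, and the median absolute deviation of 0.42 was above 17% of them. A kind of cell of fixed make-up at a larger share in replicate 2 therefore cannot be told apart from genes that vary singly.

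On chromosome 8 all 3 parts with equal numbers of genes were higher in the parental library (medians 0.35, 0.37 and 0.34), which argues against a few genes or a stretch as the source; the median fold was 1.28. An extra chromosome 8 in part of the parental cells may be the source, which RNA alone does not show. On chromosome 15 the first of 3 such parts had a median of -0.03 in fusion replicate 1 and the others 0.54 and 0.45, consistent with a single stretch. The step, placed after seeing this, lies between Nudcd1 and Eny2: 137 genes before it had a median of -0.22 and 509 genes after it 0.46. The HOXC sum was 4-fold higher in replicate 1 than in replicate 2, while genes past the step had a median fold of 1.32. Since HOXB, on another chromosome, differed 3.31-fold between the same libraries, the share of a gain of that stretch in the HOXC difference cannot be told apart from variation between these libraries.

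The 4 libraries can be split into pairs in 3 ways. The real split gave 564 genes by edgeR (3314 at an unadjusted p under 0.05), 1 of 3 with as many. The others gave 0 and 0 (119 and 278 unadjusted). Each of those splits put fusion and wild-type libraries together in both arms, so differences between fusion and wild-type counted as spread. Their low counts were therefore largely fixed in advance and give no scale for the 564. With 3 splits the share cannot fall under 0.05.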
